A study of Rattus norvegicus with 8 samples.

How the data were processed

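The deposited files hold whole UMI counts per gene and barcode, which the submitters made with Cell Ranger 6.1.1 on the genome build rn7, per the labels. The annotation release and the settings that selected barcodes are not given in the sources used here. Each library lists 20728 genes and 8333 to 12767 barcodes, the smallest with 499 to 500 UMIs. Group and replicate numbers come from the labels, and the 2 libraries of a group were not duplicates of each other (chi-square per degree of freedom 34.1 to 90.6).

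Barcodes with under 200 genes (7) or over 10% mitochondrial UMIs (2368) were removed. Doublets were predicted with Scrublet as built into scanpy 1.11.5 (Python 3.11.15) at an expected rate of 0.06, and where it marked under 0.5% of barcodes, as in both MI, both MI-soft libraries and MI-stiff replicate 1, the top 5% by score were removed. In all 4476 were removed (2.515% to 6.259% per library). Counts were scaled to 10000 per nucleus and log-transformed, 3000 variable genes were chosen, values were limited at 10, and 30 principal components, 20 neighbours, seed 1 and Leiden clustering (leidenalg 0.10.2) at resolution 1 gave the clusters. Libraries were not integrated. Clusters were named from marker lists fixed beforehand, and the names were checked on the top 10 genes of each cluster over the other classes. Clusters without a clear marker set stayed unnamed.

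UMIs were summed per library and class, for libraries with at least 10 nuclei of the class, and tested with the edgeR 4.0.16 quasi-likelihood F test (R 4.3.3) with 1 fit per class over all 8 libraries, TMM normalisation and the filterByExpr low-count filter. P-values were adjusted by Benjamini-Hochberg over the genes tested in a class and comparison, and a call is an adjusted p under 0.05. The standard error of a log2 fold change is its size divided by the square root of F. The biological coefficient of variation was 0.171 to 0.201. Folds against a group with 0 counts use a floor of 3 counts over the group, and those against 1 to 3 counts a 95% counting interval, which cover counting error only.

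The comparisons, 28 gene lists in 45 pairings of list and class, the rule for named genes and the alternatives with a plan were set before the data were examined. Lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a class and comparison, and with fry, whose results are not quoted. The rule named, per class and comparison, the 2 higher and 2 lower genes with the largest change among called genes with a mean log2 CPM of at least 5 and groups that do not overlap, or the 3 smallest p where none passed, up to 4 members per list by p, and fixed marker genes. The text names a part of these, chosen after it was seen which kept their calls, and a few further genes (Adam12, Fn1, Timp1 and others in more than 1 comparison) for reading across comparisons. Other-class markers are the naming markers of each class measured in another class.

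A gene was marked as at the level of free RNA where, in the group with the higher level, another class with at least 100 nuclei held at least 5 times its UMIs per nucleus and the class held at most 2 times the lowest level among the other main classes. The share test was an exact permutation test of the F statistic on log-ratios of shares over the 105 groupings, adjusted over 5 classes. Giant cell gene shares were taken after thinning each nucleus to 1000 UMIs (seed 11), without nuclei under 1000. The 2 gels' changes were compared with 20 simulations of unchanged groups sharing the MI libraries.

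Alternatives were relative log expression size factors in place of TMM, no low-count filter, the DESeq2 1.42.0 Wald test, the replicate number as a block, predicted doublets kept, at least 500 genes per nucleus, Leiden resolution 0.5, and each library left out in turn. Added after the data were seen were the free RNA mark, macrophage-like nuclei without cluster 17, fibroblast-like nuclei without cluster 9, unnamed clusters left out of totals, left-out libraries for correlations and remaining shares, and unthinned UMIs. The fits were tested on simulated data with 200 changed genes per comparison, built from the files' own means and spread: 14.4% to 50% of 2-fold and 67.3% to 88.8% of 4-fold changes were called, 0 with the wrong sign, and 5% to 15.6% of calls were false, above the nominal rate in most.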

Results

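Nuclei from the infarct zone of rat hearts were profiled 28 days after ligation of the left anterior descending coronary artery, an operation that starves part of the left ventricle of blood. The measurement was droplet-based 3' sequencing of nuclear RNA, counted as unique molecular identifiers (UMIs). The 4 groups held 2 libraries each: sham surgery (Sham), and infarct without a gel (MI) or with a soft (MI-soft) or stiff hydrogel (MI-stiff). MI vs Sham asks what the infarct changed, and MI-soft and MI-stiff vs MI what each gel changed in it. MI-stiff vs MI-soft asks what stiffness changed. The deposited count tables held 86715 barcodes and 20728 genes. Total UMIs per library were highest in Sham (47739782 and 47805241) and lowest in MI-stiff (24206195 and 23155204).

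Filtering for genes detected, mitochondrial share and predicted doublets kept 79871 nuclei, 7589 to 11598 per library, with a median of 1793 to 2971 UMIs per nucleus. The series description states 69608 cells and 20748 genes, and no names of single nuclei were used here. Clusters were named again from marker genes as cardiomyocyte-like, fibroblast-like, endothelial-like, macrophage-like and mural-like (smooth muscle and pericyte markers), and differences from the study's own classes may come from these rebuilt names. Most Sham nuclei of a class lay in clusters apart from infarct nuclei. Libraries were the replicates. Nothing in the labels says that the libraries came from separate animals, so p-values measure the spread between these libraries, which may be technical.

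Macrophage-like nuclei made up 5.47% ± 0.205 of nuclei in Sham (SD, n = 2 libraries in this and each following share), 6.93% ± 0.223 in MI, 12.5% ± 3.33 in MI-soft and 26% ± 2.24 in MI-stiff. Both MI-stiff libraries (24.4% and 27.6%) lay above both MI-soft libraries (10.1% and 14.9%). The 4 groups differed in an exact permutation test of the F statistic, which is 1-sided (p = 0.00952, the smallest that the 105 groupings allow; adjusted over 5 classes p = 0.0476). Without MI replicate 2 the adjusted p was 0.0952, and the left-out libraries gave 0.0476 to 0.0952. Cardiomyocyte-like nuclei made up 30.2% ± 4.75 in Sham, 3.5% ± 2.37 in MI, 4.21% ± 0.851 in MI-soft and 2.72% ± 1.15 in MI-stiff (exact permutation p = 0.105, adjusted p = 0.175). Both Sham libraries (33.6% and 26.8%) lay above all infarct libraries (1.82% to 5.17%). Other groupings that keep the Sham libraries together give a high F too, so this p does not measure that gap. Fibroblast-like shares were 28.4% ± 3.79, 39.1% ± 11.9, 46.5% ± 8.17 and 35.7% ± 4.87 in the same order of groups, and endothelial-like shares were 13.7% ± 0.819, 18% ± 3.03, 15.6% ± 2.37 and 15% ± 0.931 (both with an adjusted exact permutation p = 0.267). Mural-like shares were 9.07% ± 0.603, 6.48% ± 1.30, 5.64% ± 0.216 and 5.72% ± 0.836 (adjusted exact permutation p = 0.175). Here too both Sham libraries (8.65% and 9.5%) lay above all infarct libraries (5.13% to 7.4%), with the same limit on the p. Unnamed clusters of low depth together held 22.5% and 4.26% of the 2 MI libraries and 3.07% and 12.8% of the 2 MI-soft libraries.

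**Figure D1:**
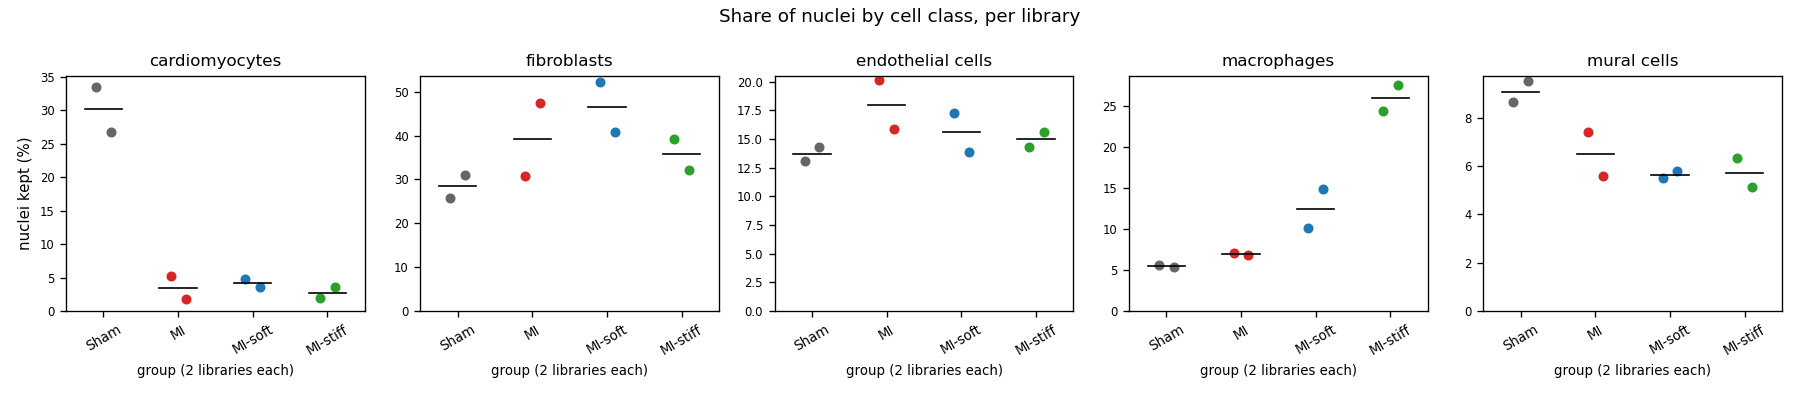
Share of kept nuclei (percent, y axis) in each of the 5 cell classes by group (x axis), where dots are libraries and lines are group means of 2 libraries. Macrophage-like nuclei rose from 5.47% in Sham to 26% in MI-stiff.

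In the paragraphs on genes, changes are log2 fold changes ± standard error with 2 libraries per group, levels are CPM (UMI counts scaled to a common, normalised library total) in the 2 libraries of a group, and a gene rose or fell when its adjusted p was under 0.05 in the edgeR quasi-likelihood test (2-sided). Gene lists were fixed before the data were examined. A list is called when the camera test against the other genes, with a preset correlation of 0.01, gave an adjusted p under 0.05.

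In cardiomyocyte-like nuclei, MI vs Sham changed 2709 of 12113 genes, 1641 higher and 1068 lower. Nppa and Nppb, the natriuretic peptide genes of the stressed ventricle, rose by 6.61 ± 0.30 (adjusted p = 3.0e-06) and 2.03 ± 0.40 (adjusted p = 0.00568). The slow myosin gene Myh7 rose by 1.36 ± 0.36 while the fast myosin gene Myh6 fell by 3.09 ± 0.42, from 11830 and 13000 CPM to 1613 and 1311. Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell by 1.46 ± 0.28. Among genes at higher levels Ildr2 had the largest rise after Nppa (5.78 ± 0.40), and Dcdc1-ps1 fell by 4.43 ± 0.77. Of the 16 stress and fetal genes, 10 rose and 0 fell (adjusted over the list alone, 13 rose), with a median of 1.37, and examples are the actin-binding repeat gene Xirp2 (2.56 ± 0.35), Fhl1 (1.73 ± 0.28) and Enah (1.39 ± 0.23). Ankrd1, a further stress gene, did not pass (0.91 ± 0.33, adjusted p = 0.0727). Of the 24 fatty acid oxidation genes, 0 rose and 14 fell (adjusted over the list alone, 16 fell), with a median of -0.86. They include Acaa2 (-1.71 ± 0.28), the carrier Slc27a1 (-2.34 ± 0.38), Hadh (-1.73 ± 0.34) and Eci1 (-1.29 ± 0.25). Of the 23 nuclear-encoded oxidative phosphorylation genes 3 fell (1 adjusted over the list alone; median -0.38). Of the 22 ion channel and gap junction genes 2 rose and 8 fell (4 and 12 adjusted over the list alone; median -0.63). Of the 15 immediate early and heat shock genes 11 rose (11 adjusted over the list alone; median 1.51), Klf6 by 2.12 ± 0.22. Of the 10 interferon response genes 5 rose (5 adjusted over the list alone; median 1.15), Ifi27 by 1.53 ± 0.35.

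The camera adjusted p in these nuclei was 1.53e-09 for stress and fetal genes, 4.82e-08 for fatty acid oxidation, 2.99e-06 for immediate early and heat shock, 0.00991 for oxidative phosphorylation, 0.0111 for ion channels and 0.0311 for interferon response. Each call was lost: adjusted p = 0.369, 0.423, 0.369, 0.623, 0.38 and 0.38 with an estimated correlation, in the same order. The other 5 lists were not called. Of 24 sarcomere genes 3 rose and 2 fell (median -0.15, adjusted p = 0.299). Of 16 calcium handling genes 2 rose and 2 fell (median -0.19, adjusted p = 0.237), and of 20 glycolysis genes 2 rose and 5 fell (5 and 6 adjusted over the list alone), Pfkm by -1.23 ± 0.23 (median -0.13, adjusted p = 0.297). Of 31 mechanotransduction genes 8 rose and 2 fell (11 and 3 adjusted over the list alone). The YAP target Ccn2 rose by 4.63 ± 0.39, Zyx by 1.76 ± 0.28 and Itgb1 by 1.49 ± 0.24, and the list's mean of 0.48 and its test pointed up while its median was -0.01 (adjusted p = 0.0995). Of 17 hypoxia genes 2 rose and 1 fell (3 and 1 adjusted over the list alone; median 0.19, adjusted p = 0.873). Sham cardiomyocyte-like nuclei numbered 3893 and 2738 per library and those of infarct libraries 145 to 585. Markers of fibroblasts were higher in these nuclei too (median 2.53, 9 of 11 rose), as were those of macrophages (1.61, 4 rose), endothelial (1.44, 7 rose) and smooth muscle cells (1.60, 5 rose).

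In the same nuclei the number of changed genes was 1463 without MI replicate 1, 1265 without MI replicate 2, 1250 without Sham replicate 1 and 1429 without Sham replicate 2. Myh7 lost its call without MI replicate 1 (1.07) and without Sham replicate 1 (1.04), Atp2a2 without MI replicate 2 (-1.36), and Ifi27 without MI replicate 1 (1.25) or Sham replicate 1 (1.23). Without MI replicate 1, Dcdc1-ps1 was at -6.48, Acaa2 at -2.32 and Slc27a1 at -3.5, and without Sham replicate 2 Nppb was at 2.97. The interferon list lost its call without MI replicate 1 (median 0.96, adjusted p = 0.0528) and the oxidative phosphorylation list without MI replicate 2 (median -0.25, adjusted p = 0.0761).

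**Figure D2:**
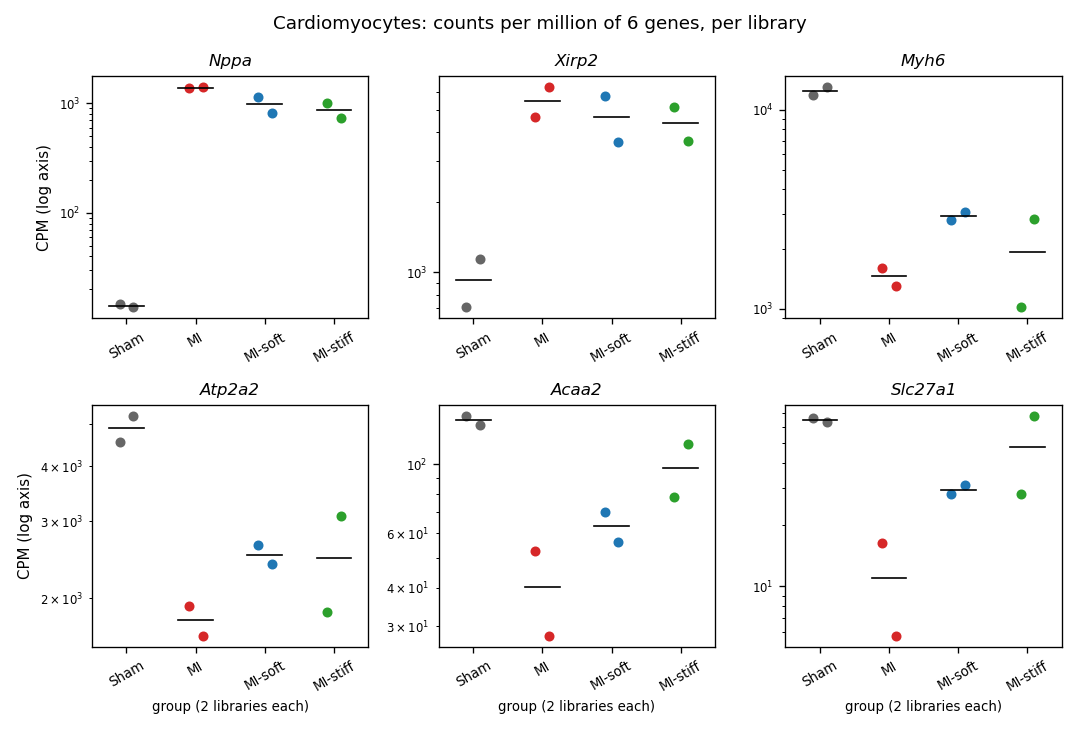
Levels of 6 genes in cardiomyocyte-like nuclei (CPM, log y axis) by group (x axis), where dots are libraries and lines are means of 2 libraries. Nppa stood at 14.6 and 13.8 CPM in Sham and between 730 and 1412 in the 6 infarct libraries.

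In fibroblast-like nuclei, MI vs Sham changed 3158 of 15441 genes, 1861 higher and 1297 lower. Postn, which marks activated cardiac fibroblasts, rose by 1.36 ± 0.21 (adjusted p = 0.00355), from 48.8 and 36 CPM to 129 and 88.9. The fibrillar collagen genes Col1a1 and Col3a1 rose by 1.64 ± 0.27 and 1.23 ± 0.19. Comp, a cartilage matrix gene of mature scar fibroblasts, rose by 7.58 ± 0.47 (adjusted p = 1.2e-04), and Cilp by 2.38 ± 0.41. The largest rises at higher levels were those of Spp1 (8.23 ± 0.99), a secreted matrix protein, and Col11a1 (7.74 ± 0.72), and the largest fall that of Blnk (-5.44 ± 0.43). Of the 18 activated fibroblast genes 14 rose and 1 fell (15 and 2 adjusted over the list alone; median 2.30), among them Fn1 (2.37 ± 0.22), Ltbp2 (5.37 ± 0.29), Runx1 (4.16 ± 0.23) and Runx2 (2.95 ± 0.13). Of the 14 matrifibrocyte and cartilage-like genes 13 rose (13 adjusted over the list alone; median 4.95). Of the 35 collagen and matrix genes 16 rose and 1 fell (19 and 3 adjusted over the list alone; median 0.66), Bgn by 2.42 ± 0.20. Of the 15 homeostatic fibroblast genes 1 rose, Pi16 (2.34 ± 0.30), and 8 fell (1 and 9 adjusted over the list alone; median -0.88), among them Abca8a (-3.06 ± 0.32), the transcription factor gene Ebf2 (-1.15 ± 0.18) and Lama2 (-1.31 ± 0.20). Of the 21 TGF-beta genes 10 rose and 2 fell (11 and 4 adjusted over the list alone; median 0.65), Tgfb3 by 1.06 ± 0.15 and the inhibitor gene Skil by 1.14 ± 0.14. Of the 17 interferon response genes 10 rose (14 adjusted over the list alone; median 1.26), Bst2 by 1.26 ± 0.21.

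Camera called 6 of the 10 fibroblast lists. The calls of the activated (adjusted p = 2.39e-17), matrifibrocyte (1.19e-18) and TGF-beta (2.38e-04) lists held with an estimated correlation (0.0189, 0.00795 and 0.0469). Those of the collagen (5.31e-09), homeostatic (7.87e-05) and interferon (9.13e-05) lists were lost, with adjusted p = 0.0618, 0.184 and 0.351 with an estimated correlation. Of 17 matrix proteases and inhibitors 7 rose and 3 fell (8 and 5 adjusted over the list alone; median 0.45, adjusted p = 0.0719, and 0.044 without cluster 9): the inhibitor genes Timp1 and Timp3 rose by 2.92 ± 0.18 and 3.40 ± 0.23, and the protease genes Adamts12 and Adamts5 fell by 2.03 ± 0.18 and 1.90 ± 0.23. Of 32 mechanotransduction genes 5 rose and 4 fell (7 and 5 adjusted over the list alone), with the stretch-gated channel gene Piezo2 at 4.22 ± 0.22, Ccn2 at 4.62 ± 0.49 and Tln2 at -1.35 ± 0.14; the median was -0.08 where the mean of 0.28 and the test pointed up (adjusted p = 0.913). Of 20 hypoxia genes 3 rose and 1 fell (5 and 2 adjusted over the list alone; median 0.02, adjusted p = 0.804), Ldha by 1.38 ± 0.19. Of 20 immediate early and heat shock genes 4 rose (4 adjusted over the list alone; median 0.39, adjusted p = 0.0719), Junb by 1.12 ± 0.14. Markers of mesothelial (median 5.18, 4 of 4 rose), endocardial (2.32, 4 rose) and smooth muscle cells (2.04, 7 rose) and of macrophages (1.65, 7 rose) were higher in these nuclei and those of cardiomyocytes lower (median -0.95). The number of changed genes was 1678 without MI replicate 2, 1762 without Sham replicate 1 and 1576 without Sham replicate 2. Each gene named kept its call in each case, but was chosen with this known. Cilp was at 3.24 and Ccn2 at 5.36 without Sham replicate 1, and Col11a1 at 6.99 without MI replicate 1.

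In endothelial-like nuclei, MI vs Sham changed 958 of 13071 genes, 530 higher and 428 lower. Cdh23 and Lnx1 had the largest falls at higher levels (-2.43 ± 0.26, adjusted p = 0.00321, and -2.27 ± 0.26, adjusted p = 0.00448). Tie1, an endothelial receptor gene, fell by 1.18 ± 0.17 (adjusted p = 0.00582). The venous adhesion gene Selp rose by 2.91 ± 0.39, and the mesenchymal genes Col1a1 and Col3a1 by 2.73 ± 0.34 and 2.54 ± 0.34. Esm1, a gene of sprouting tip cells, was 10.8 times higher (95% counting interval 3.53 to 53.7). The fixed genes Vwf (-0.12 ± 0.30), Kdr (-0.39 ± 0.16) and Flt1 (-0.34 ± 0.25) did not pass. Nppa rose by 6.46 ± 0.68, to 1443 and 989 CPM against 1369 and 1412 CPM in cardiomyocyte-like nuclei.

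Of the 28 angiogenesis genes 3 rose and 3 fell (3 and 4 adjusted over the list alone; median -0.33, camera adjusted p = 0.0102), with Angpt1 at -2.49 ± 0.18, a gene whose level matched free RNA from other classes. Of the 9 capillary and lipid uptake genes 1 fell (1 adjusted over the list alone; median -0.59, adjusted p = 0.0179). Of the 13 mesenchymal transition genes 6 rose and 1 fell (6 and 1 adjusted over the list alone; median 0.54, adjusted p = 2.02e-04), 3 of them at the level of free RNA, and of the 11 adhesion and inflammation genes 3 rose (5 adjusted over the list alone; median 0.70, adjusted p = 0.00123). None of 18 immediate early and heat shock genes passed (0 adjusted over the list alone; median 0.58, adjusted p = 0.0172). All 5 calls were lost, with adjusted p = 0.26, 0.674, 0.141, 0.26 and 0.674 with an estimated correlation. Of 32 mechanotransduction genes 2 rose and 2 fell, Piezo2 by 1.32 ± 0.17 (median 0.02 with a test pointing down, adjusted p = 0.856). Of 19 hypoxia genes 1 rose and 2 fell (1 and 3 adjusted over the list alone; median -0.03), and of 17 interferon response genes 0 passed (median 0.24; adjusted p = 0.358 each). Fibroblast markers were higher in these nuclei (median 1.61, 7 of 12 rose) and cardiomyocyte markers lower (-1.70, 4 of 11 fell), and the medians of smooth muscle and macrophage markers were 1.5 (4 of 8 rose) and 1.27 (2 of 12 rose). Without genes at the level of free RNA, 643 genes passed, 69.05% of them higher, against 55.32% of all 958.

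The endothelial-like count rested on the Sham libraries. It was 60 without Sham replicate 1, 207 without Sham replicate 2, 365 without MI replicate 2 and 1538 without the low-count filter. Without Sham replicate 1 the calls of Tie1 (-1.22), Esm1, Col1a1 (2.86), Col3a1 (2.63), Selp (2.41) and Piezo2 (1.28) ended, and without Sham replicate 2 those of Tie1 (-1.13), Esm1 and Col3a1 (2.46), with Selp at 3.83. Esm1 also lost its call without MI replicate 2, and Flt1 passed without MI replicate 1 (-0.79). Cdh23, Lnx1, Angpt1 and Nppa kept theirs in each case. The immediate early list lost its call without MI replicate 1 (median 0.24, adjusted p = 0.443), the angiogenesis list without MI replicate 2 (median -0.25, adjusted p = 0.177), and the capillary list without MI replicate 2 (median 0.00, adjusted p = 0.712) or Sham replicate 2 (median -0.62, adjusted p = 0.126).

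In macrophage-like nuclei, MI vs Sham changed 778 of 12212 genes, 459 higher and 319 lower. Gpnmb, a gene of lipid-laden and scar-associated macrophages, rose by 2.27 ± 0.20 (adjusted p = 0.00111), from 74.2 and 85.1 CPM to 380 and 387. Cd9 rose by 3.71 ± 0.28 (adjusted p = 0.00111), Spp1 by 4.56 ± 0.73 and the lysosomal protease gene Ctsk by 1.86 ± 0.33. Ppp2r2b and Col19a1 fell by 3.79 ± 0.35 and 3.81 ± 0.76. Comp, a fibroblast gene, was at least 25.3-fold higher (floor of 3 counts over the Sham group). Markers of resident macrophages did not pass, with Lyve1 at 0.62 ± 0.38, Cd163 at 0.35 ± 0.36 and Folr2 at -0.53 ± 0.16, nor did the monocyte receptor gene Ccr2 (0.30 ± 0.59). Of the 18 lipid- and fibrosis-associated genes 8 rose (10 adjusted over the list alone; median 1.25, or 1.15 with genes absent from Sham at their bound; adjusted p = 2.48e-09), and of the 16 interferon response genes 3 rose (3 adjusted over the list alone; median 1.23, adjusted p = 1.8e-04), Ifi27 by 1.28 ± 0.26. Both calls were lost, with adjusted p = 0.243 and 0.518 with an estimated correlation.

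The other 7 lists were not called in macrophage-like nuclei. None of 16 resident genes passed (median 0.34, adjusted p = 0.382), 1 of 16 inflammatory monocyte genes rose (median -0.12, mean 0.18 and test up, adjusted p = 0.474), and 2 of 9 osteoclast-like and giant cell genes rose (median 1.80, adjusted p = 0.0537). None of 8 antigen presentation genes passed (median -0.03, adjusted p = 0.525). Of 31 mechanotransduction genes 2 rose and 3 fell (2 and 5 adjusted over the list alone; median -0.23, mean 0.02, adjusted p = 0.21). Of 17 hypoxia genes 2 rose and 2 fell (3 and 2 adjusted over the list alone; median 0.34, adjusted p = 0.474), and of 17 immediate early and heat shock genes 1 rose (median 0.35, adjusted p = 0.189). Smooth muscle (median 2.86, 4 rose) and fibroblast markers (2.00, 9 rose) were higher in these nuclei and cardiomyocyte markers lower (median -1.30). Without genes at the level of free RNA 417 genes passed, 76.74% of them higher against 59.00% of all 778. The count was 472 without MI replicate 1, 361 without MI replicate 2, 91 without Sham replicate 1 and 231 without Sham replicate 2. Ppp2r2b, Cd9 and Gpnmb kept their calls in each case. Without Sham replicate 1 those of Comp, Col19a1 (-4.31), Spp1 (3.56), Ctsk (1.48) and Ifi27 (0.98) ended, and without Sham replicate 2 that of Col19a1 (-3.06), with Spp1 at least 40.1-fold higher. Without MI replicate 1 those of Col19a1 (-2.94) and Ifi27 (1.19) ended, and without MI replicate 2 those of Ctsk (1.75) and Ifi27 (1.36), with Col19a1 at -5.85 and the interferon list uncalled (median 0.28, adjusted p = 0.156). Without cluster 17 Ctsk lost its call too (1.91), and Spp1 was at least 45.7-fold higher.

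In mural-like nuclei, MI vs Sham changed 2599 of 11511 genes, 1509 higher and 1090 lower. The contractile smooth muscle genes Acta2 and Myh11 rose by 3.61 ± 0.32 (adjusted p = 6.2e-05) and 2.88 ± 0.29 (adjusted p = 1.1e-04), Acta2 from 78.9 and 86.1 CPM to 856 and 1162. Pericyte genes fell: Rgs5 by 1.18 ± 0.29 (adjusted p = 0.0119), the potassium channel genes Kcnj8 and Abcc9 by 1.82 ± 0.30 and 1.83 ± 0.34, and the proteoglycan gene Cspg4 by 1.79 ± 0.27. The matrix gene Ccn3 was at least 66.9-fold higher, and Tafa2 fell by 4.94 ± 1.13. Of the 35 collagen and matrix genes 27 rose and 0 fell (29 rose adjusted over the list alone; median 2.68), among them Col8a1 (4.88 ± 0.31), Bgn (3.5 ± 0.25), Col12a1 (2.53 ± 0.22) and Vcan (2.64 ± 0.23). This call (adjusted p = 6.55e-31) held with an estimated correlation (0.0246). Of the 17 contractile genes 13 rose (15, with 1 lower, adjusted over the list alone; median 1.93, adjusted p = 8.49e-16), Tagln by 4.07 ± 0.39 and Lmod1 by 3.70 ± 0.29, and of the 12 pericyte genes 9 fell (9 adjusted over the list alone; median -1.23, adjusted p = 1.42e-06). These 2 calls were lost, with adjusted p = 0.085 and 0.252 with an estimated correlation.

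Among the mural-like lists not called, 7 of 31 mechanotransduction genes rose and 2 fell (median 0.06, adjusted p = 0.0952), with Ccn2 at 4.62 ± 0.51 and the channel gene Piezo1 at 2.08 ± 0.35. Of 17 hypoxia genes 5 rose and 1 fell (6 and 2 adjusted over the list alone; median 0.40, adjusted p = 0.0538), Ndrg1 by 2.06 ± 0.33 and Hif1a by 1.12 ± 0.19. Of 13 interferon response genes 5 rose (6 adjusted over the list alone; median 0.97, adjusted p = 0.07), Bst2 by 1.81 ± 0.33. Of 15 immediate early and heat shock genes 6 rose (7 adjusted over the list alone; median 0.69, adjusted p = 0.0538), Junb by 2.08 ± 0.30. Markers of fibroblasts (median 2.29, 9 rose and 1 fell), endocardial (2.21, 3 rose), Schwann (1.85, 3 rose) and endothelial cells (0.68, 5 rose) and macrophages (1.31, 6 rose) were higher in these nuclei, and those of cardiomyocytes lower (-1.33, 3 fell). The count was 1727 without MI replicate 2, 1692 without Sham replicate 1 and 1500 without Sham replicate 2. Rgs5 lost its call without MI replicate 2 (-1.09) or Sham replicate 2 (-0.91). Tafa2 was at -4.09 without MI replicate 2, and without MI replicate 1 it had 1 UMI in MI and was at least 249-fold lower by the 95% counting interval.

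Over the 10357 genes tested in all 5 classes, 115 rose and 42 fell in each of the 5 in MI vs Sham. Without genes at the level of free RNA in any class, 69 rose and 1, the splicing factor gene Hnrnpdl, fell. The higher ones include the scar genes Comp, Sfrp2, Thbs4, Col1a1 and Timp1, the antigen presentation gene B2m, and the chaperone genes Hspa5, Hsp90b1, Calr and Hspa8. Nppa, also among the 69, rose by 6.46 to 7.52 across the classes and stood in endothelial-like nuclei near its cardiomyocyte-like level, and fibroblast markers rose in the other 4 classes (medians 2.53, 1.61, 2.00 and 2.29). The mark thus leaves free RNA open for the scar genes and Nppa. In the gel comparisons 0 genes passed in all 5 classes by the edgeR test.

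In macrophage-like nuclei, MI-soft vs MI changed 545 genes, 412 higher and 133 lower. Genes of osteoclasts and fused giant cells rose: the fusion receptor genes Dcstamp by 3.92 ± 0.41 (adjusted p = 0.00122) and Ocstamp 63.5 times (95% counting interval 17.4 to 527), Tm4sf19 by 5.08 ± 0.42 (adjusted p = 6.6e-04), from 7.71 and 11.7 CPM to 380 and 272, and Ctsk by 2.23 ± 0.22. Dnah3 was at least 119-fold higher, and the kinase gene Prkcz fell by 2.81 ± 0.44. Of the 9 osteoclast-like and giant cell genes 5 rose (6 adjusted over the list alone; median 2.23), and this call (adjusted p = 3.0e-22) held with an estimated correlation (0.00446). Of the 18 lipid- and fibrosis-associated genes 7 rose (12 adjusted over the list alone; median 0.95), among them Gpnmb (1.69 ± 0.18), the lipid droplet gene Plin2 (1.72 ± 0.19), Lgals3 (1.65 ± 0.23), Mmp12 (4.57 ± 0.48) and Spp1 (3.25 ± 0.48). Of the 16 resident genes 5 fell (9 adjusted over the list alone; median -0.90), Maf by 1.62 ± 0.26 and the mannose receptor gene Mrc1 by 1.37 ± 0.26, while Lyve1 did not pass (-1.50 ± 0.37, adjusted p = 0.056). Of 17 hypoxia genes 2 rose (3 adjusted over the list alone; median 0.20), Ndrg1 by 1.76 ± 0.17. Of 16 interferon response genes 2 fell (2 adjusted over the list alone; median -0.81). Of 17 immediate early and heat shock genes 3 rose (5 adjusted over the list alone; median 0.52), Atf3 by 2.61 ± 0.27.

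The calls of the lipid (adjusted p = 1.16e-13), resident (1.63e-08), interferon (2.36e-04), immediate early (3.63e-04) and hypoxia (0.0124) lists in MI-soft vs MI were lost, with adjusted p = 0.066, 0.23, 0.35, 0.349 and 0.424 with an estimated correlation. The inflammatory list (median 0.44, 3 rose and 1 fell, 3 and 2 adjusted over the list alone), with the monocyte cytokine gene Il1b at -1.50 ± 0.29, the antigen presentation list (median 0.27) and the mechanotransduction list (median 0.20, 3 rose, 5 and 2 adjusted over the list alone) were not called, at adjusted p = 0.422 or more. Without cluster 17, a macrophage-like cluster with 8 and 5 nuclei in MI, 143 and 204 in MI-soft and 503 and 517 in MI-stiff, 1 gene passed. Then none of the genes named for MI-soft vs MI passed. Mmp12 (4.99) and Spp1 (3.36) were no smaller, with larger errors, and with 0 UMIs in MI Dnah3 and Ocstamp were at least 5.66-fold and 15.1-fold higher. Others were smaller, with Tm4sf19 at 2.22, Ctsk at 1.21, Dcstamp at 2.05, Gpnmb at 0.88, Plin2 at 0.69, Lgals3 at 0.93, Prkcz at -2.32, Il1b at -1.0, Ndrg1 at 1.04, Atf3 at 1.61, Maf at -1.24 and Mrc1 at -0.89. The osteoclast list kept its call (median 1.21, adjusted p = 4.13e-06), and the antigen presentation (0.72, 1.39e-04) and inflammatory lists (0.48, 0.0192) became called higher. The naming markers of macrophages fell in MI-soft vs MI (median -0.84, 6 of 12 fell). The count was 248 without MI replicate 1, 215 without MI replicate 2, 218 without MI-soft replicate 1 and 303 without MI-soft replicate 2. Without MI replicate 2 the calls of Prkcz (-2.26), Spp1 (2.87) and Il1b (-1.61) ended, and without MI replicate 1 those of Mrc1 (-1.11) and Il1b (-1.33). Without MI-soft replicate 1 that of Mrc1 (-1.58) ended, and without MI-soft replicate 2 those of Prkcz (-2.36), Maf (-1.47), Mrc1 (-1.19) and Il1b (-1.19). Without MI replicate 1, Dcstamp was at 3.16, Mmp12 at 3.78, Spp1 at 3.84 and Ocstamp 29.1 times higher (95% counting interval 7.99 to 242). Without MI replicate 2, Mmp12 was at 6.20, Dcstamp 37.9 times higher (12.9 to 184) and Ocstamp at least 22.9-fold. The hypoxia list lost its call without MI replicate 2 (median 0.11), MI-soft replicate 2 (median 0.11) or the low-count filter (median 0.19, adjusted p = 0.053), and the interferon list without MI replicate 2 (median 0.00, adjusted p = 0.552).

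MI-stiff vs MI changed 1641 genes in macrophage-like nuclei, 997 higher and 644 lower. Dcstamp rose by 4.72 ± 0.40 (adjusted p = 2.0e-04), Tm4sf19 by 5.40 ± 0.42 (adjusted p = 1.5e-04) and Ctsk by 2.96 ± 0.22, from 32.9 and 37.6 CPM to 260 and 290, and Ocstamp was 119 times higher (95% counting interval 32.9 to 986). Dnah3 was at least 223-fold and the exchange factor gene Rasgrf1 at least 62.9-fold higher, and Prkcz and the leukotriene synthase gene Ltc4s fell by 4.31 ± 0.46 and 3.53 ± 0.48. Of the osteoclast-like and giant cell genes 6 of 9 rose (7 adjusted over the list alone; median 2.96, adjusted p = 4.5e-17, and 0.00757 with an estimated correlation). Of the lipid- and fibrosis-associated genes 9 of 18 rose (13 adjusted over the list alone; median 1.04), Plin2 by 2.34 ± 0.19, Gpnmb by 2.24 ± 0.19, Lgals3 by 2.10 ± 0.23, Mmp12 by 5.58 ± 0.48 and Spp1 by 3.21 ± 0.48. Of the resident genes 8 of 16 fell (10 adjusted over the list alone; median -1.16): the scavenger receptor genes Stab1 by 3.06 ± 0.33 and Cd163 by 2.40 ± 0.38, Lyve1 by 2.47 ± 0.38, Maf by 2.00 ± 0.26 and Mrc1 by 1.76 ± 0.26. Of the interferon response genes 7 of 16 fell (8 adjusted over the list alone; median -1.14), the RNA sensor gene Ifih1 by 1.33 ± 0.21 and Ifi27 by 1.16 ± 0.23. Of the hypoxia genes 4 of 17 rose (5 adjusted over the list alone; median 0.53), Ndrg1 by 2.44 ± 0.17 and the glucose carrier gene Slc2a1 by 3.29 ± 0.41. Of the immediate early and heat shock genes 5 of 17 rose (7, with 1 lower, adjusted over the list alone; median 0.62), Atf3 by 3.13 ± 0.27 and Egr2 by 3.64 ± 0.41. Of the 8 antigen presentation genes 1 rose (4 adjusted over the list alone; median 0.83), the class II transactivator gene Ciita (1.90 ± 0.50).

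The calls of the lipid (adjusted p = 1.1e-12), resident (1.84e-08), interferon (9.15e-05), hypoxia (1.03e-04), immediate early (2.55e-04) and antigen (0.0355) lists in MI-stiff vs MI were lost, with adjusted p = 0.0795, 0.203, 0.259, 0.259, 0.259 and 0.492 with an estimated correlation. The inflammatory list was not called (4 rose and 3 fell, 6 and 4 adjusted over the list alone; median 0.04 while the mean of -0.43 and the test pointed down, adjusted p = 0.986), with Nlrp3 and Il1b, genes of the inflammasome pathway, at -1.78 ± 0.24 and -1.75 ± 0.28 and the integrin gene Itgax at 1.97 ± 0.23. Nor was the mechanotransduction list (3 rose and 4 fell, 5 and 5 adjusted over the list alone; median -0.12, adjusted p = 0.324), with the adhesion gene Vcl at 2.21 ± 0.18, Pxn at -1.26 ± 0.17 and the stretch-sensitive channel gene Trpv4 at -1.77 ± 0.24. Without cluster 17, 288 genes passed. Calls ended for Dnah3 (at least 8.25-fold higher), Ocstamp (at least 13.2-fold higher), Ctsk (1.75), Dcstamp (2.75), Mrc1 (-1.02), Cd163 (-1.68), Itgax (1.01), Nlrp3 (-1.06), Il1b (-1.10), Pxn (-0.71), Ifih1 (-0.99) and Ifi27 (-0.78). Calls remained for Tm4sf19 (2.69), Plin2 (1.23), Lgals3 (1.35), Vcl (1.22), Egr2 (2.30), Gpnmb (1.73), Stab1 (-2.32), Lyve1 (-1.78) and Ndrg1 (1.91). The osteoclast list kept its call (median 1.75, adjusted p = 1.53e-07), and the antigen list moved further up (1.53, 7.25e-11). The naming markers of macrophages fell in MI-stiff vs MI (median -0.79, 8 of 12 fell and 1 rose), and the median of dividing-cell markers was 1.13 with either gel (1 of 8 rose). The count was 919 without MI replicate 1, 851 without MI replicate 2 and 868 without MI-stiff replicate 1. Ciita lost its call without MI replicate 1 (1.54), MI replicate 2 (2.35) or MI-stiff replicate 1 (1.19), and Ifi27 without MI replicate 1 (-1.06) or MI-stiff replicate 1 (-0.93). The antigen list lost its call without MI replicate 1 (median 0.54, adjusted p = 0.19) or MI-stiff replicate 1 (median 0.62, adjusted p = 0.143), and the interferon list without MI replicate 2 (median -0.38, adjusted p = 0.086). Without MI replicate 1, Dcstamp was at 3.95, Mmp12 at 4.77 and Ocstamp 54.8 times higher (95% counting interval 15.1 to 453). Without MI replicate 2, Mmp12 was at 7.19, Dcstamp 67.8 times higher (23.1 to 329) and Ocstamp at least 43-fold. Without MI-stiff replicate 2 Prkcz was at -5.11, Ltc4s at -4.12 (-2.70 without MI replicate 2), Stab1 at -3.69, Lyve1 at -3.28 and Cd163 at -3.20, and Rasgrf1 was at least 28.2-fold higher without MI-stiff replicate 1.

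MI-stiff vs MI-soft gave 0 genes in macrophage-like nuclei by the edgeR test, 1138 at an unadjusted p under 0.05 and 66 by DESeq2. The smallest p belonged to Plekhg5 (-1.40 ± 0.19), Astn2 (1.54 ± 0.21) and Fstl1 (-1.07 ± 0.16), with adjusted p = 0.131, 0.131 and 0.132. Stab1 was at -1.61 ± 0.32, Ctsk at 0.73 ± 0.19 and Spp1 at -0.03 ± 0.43. Without MI-stiff replicate 2, 51 genes passed, Astn2, Fstl1 and Stab1 among them. No member of a list passed over all genes. Lists were called higher for osteoclast-like (median 0.38, 3 rose adjusted over the list alone, adjusted p = 0.00434), lipid (0.30, 0.00246), antigen presentation (0.61, 0.00434) and hypoxia genes (0.37, 8.47e-04), and lower for resident (-0.37, 0.00452), mechanotransduction (-0.20, 0.00153) and interferon genes (-0.31, 0.0447). All 7 calls were lost, with adjusted p = 0.199 to 0.436 with an estimated correlation. Calls ended for the resident and antigen lists without MI-soft replicate 1 or MI-stiff replicate 1, for hypoxia without MI-soft replicate 1, and for the lipid list without MI-stiff replicate 2 (median -0.14). The interferon call ended without MI-soft replicate 1, MI-stiff replicate 1, MI-stiff replicate 2 or cluster 17 and with predicted doublets kept. The inflammatory and immediate early lists were not called (adjusted p of 0.0538 or more).

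A UMI of any of 4 giant cell genes, Tm4sf19, Atp6v0d2, Dcstamp and Ocstamp, chosen after their values were seen, was found in 0.617% ± 0.528 of macrophage-like nuclei in Sham (SD, n = 2), 1.11% ± 0.50 in MI, 16% ± 1.59 in MI-soft and 25.1% ± 3.40 in MI-stiff, with each nucleus thinned to 1000 UMIs. No test was run on them. The share in endothelial-like nuclei, a class that should lack these genes, was 0%, 0.151%, 1.17% and 1.82% in the same order. Unthinned shares were 0.706%, 1.83%, 18.7% and 29.5% in macrophage-like nuclei and 0.0675%, 0.347%, 2.51% and 3.64% in endothelial-like nuclei.

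**Figure D3:**
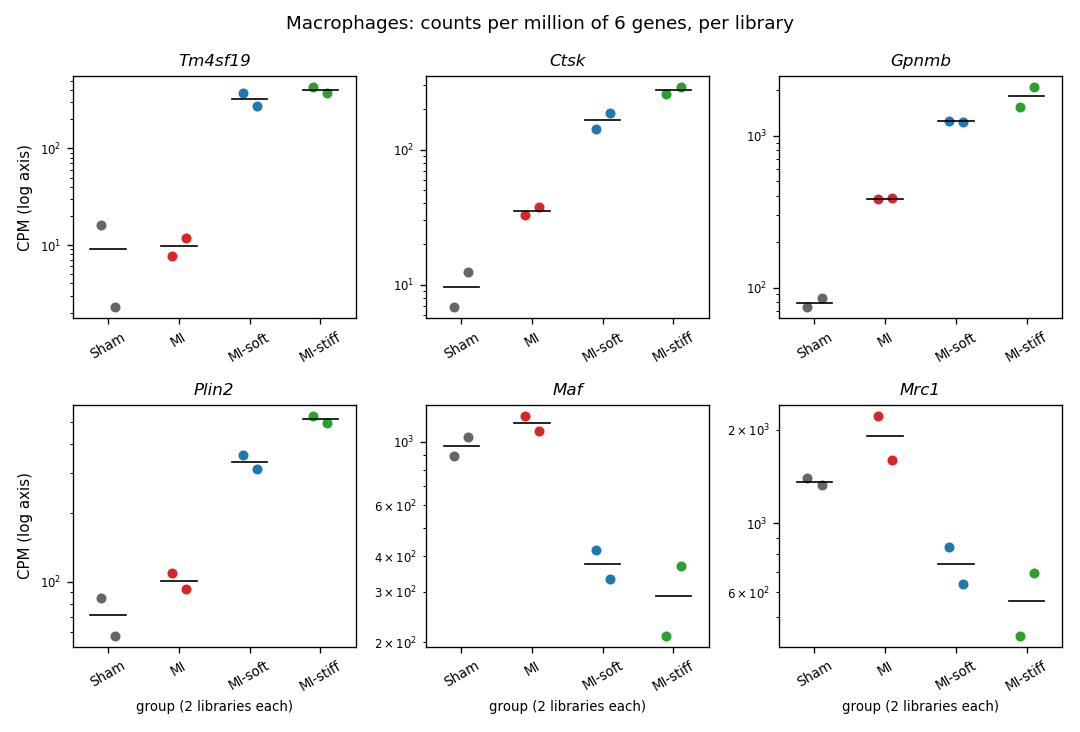
Levels of 6 genes in macrophage-like nuclei (CPM, log y axis) by group (x axis), where dots are libraries and lines are means of 2 libraries. Tm4sf19 stood between 2.27 and 15.97 CPM in the Sham and MI libraries and between 272 and 433 in the gel libraries, and Maf between 889 and 1232 and between 211 and 419.

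In fibroblast-like nuclei, MI-soft vs MI changed 8 genes, 7 higher and 1 lower, against 261 by DESeq2 and 18 without the low-count filter. The matricellular genes Tnn and Tnc, which are made in wounds, rose by 3.65 ± 0.37 (adjusted p = 0.0158) and 2.18 ± 0.18 (adjusted p = 0.00887), Tnc from 10.8 and 11.1 CPM to 50 and 49.3. Fn1 was at 1.59 ± 0.21, Timp1 at 1.13 ± 0.15 and the protease gene Mmp3 at least 20.7-fold higher, each with an adjusted p = 0.0666, and Postn was at 1.05 ± 0.21 (adjusted p = 0.128). Of the 35 collagen and matrix genes 1 rose (13 adjusted over the list alone; median 0.54, adjusted p = 1.99e-17), and of the 17 matrix proteases and inhibitors 0 passed (4 rose adjusted over the list alone; median 0.31, adjusted p = 2.5e-06). Both calls held with an estimated correlation (0.0357 each). Calls of the activated list (1 rose, 6 adjusted over the list alone; median 0.39, adjusted p = 7.79e-07), TGF-beta (1 rose adjusted over the list alone; median 0.15, adjusted p = 0.0231), immediate early (4 rose adjusted over the list alone; median 0.46, adjusted p = 6.01e-05) and interferon lists (median -0.53, adjusted p = 0.00383) were lost, with adjusted p = 0.1, 0.136, 0.199 and 0.448 with an estimated correlation. The other 4 lists were not called (adjusted p of 0.053 or more). The count was 2 without MI replicate 1, 0 without MI replicate 2, 4 without MI-soft replicate 2, 2 without Sham replicate 2 and 4 without cluster 9, where the mechanotransduction list became called (median 0.10, adjusted p = 0.0486). Tnn lost its call without MI replicate 1 (3.81), MI replicate 2 (3.51), Sham replicate 2 (3.66) or cluster 9 (2.64), and Tnc lost it without MI replicate 1 (2.16), MI replicate 2 (2.20) or cluster 9 (1.65). The TGF-beta list lost its call without MI replicate 1 (median 0.15, adjusted p = 0.178) or MI-soft replicate 2 (median 0.09, adjusted p = 0.0526), and the interferon list without MI replicate 2, where its median was 0.04.

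MI-stiff vs MI changed 491 genes in fibroblast-like nuclei, 401 higher and 90 lower, against 805 by DESeq2. Tnn and Tnc rose by 5.57 ± 0.39 (adjusted p = 8.5e-04) and 3.47 ± 0.18 (adjusted p = 2.6e-04), Postn by 2.79 ± 0.22 (adjusted p = 0.00114), from 129 and 88.9 CPM to 749 and 762, Fn1 by 2.82 ± 0.22 and the protease gene Adam12 by 2.89 ± 0.27. Timp1 rose by 2.22 ± 0.16, and Mmp3 was at least 99.8-fold higher (0 UMIs in MI, 196 in MI-stiff). Gpc3 and Dpep1, genes of quiescent fibroblasts, fell by 2.49 ± 0.45 and 1.56 ± 0.23. The main scar collagen genes did not pass, with Col1a1 at 0.69 ± 0.27 (adjusted p = 0.232) and Col3a1 at 0.25 ± 0.18, nor did Comp (-0.05 ± 0.27) and Cilp (-0.18 ± 0.38). Of the 18 activated genes 7 rose (10 adjusted over the list alone; median 0.70, adjusted p = 1.26e-16), Runx2 by 0.82 ± 0.12. Of the 35 collagen and matrix genes 6 rose (11 adjusted over the list alone; median 0.43, adjusted p = 1.68e-14), Col6a3 by 0.97 ± 0.13. Of the 17 proteases and inhibitors 2 rose (6 adjusted over the list alone; median 0.35, adjusted p = 1.99e-08). These 3 calls held with an estimated correlation (0.0324, 0.0372 and 0.0324). Calls of the hypoxia (2 rose, 5 adjusted over the list alone; median 0.30, adjusted p = 7.97e-04), immediate early (3 rose, 4 adjusted over the list alone; median 0.45, adjusted p = 5.29e-04), interferon (median -0.45, adjusted p = 6.88e-04), homeostatic (1 fell, 3 adjusted over the list alone; median -0.32, adjusted p = 0.00264) and matrifibrocyte lists (1 fell adjusted over the list alone; median -0.44, adjusted p = 0.0134) were lost, with adjusted p = 0.146, 0.226, 0.364, 0.259 and 0.146 with an estimated correlation. The TGF-beta (median 0.08) and mechanotransduction lists (median -0.01 while the mean of 0.13 and the test pointed up) were not called (adjusted p of 0.405 or more).

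In the same comparison, cluster 9, a fibroblast-like cluster with 60 and 52 nuclei in MI, 287 and 454 in MI-soft and 1038 and 990 in MI-stiff, was also left out, and 5 genes passed. Tnn (3.95) and Timp1 (1.49) kept their calls, and those of Tnc (1.32), Postn (1.28), Fn1 (1.66), Adam12 (0.79), Runx2 (0.02), Col6a3 (0.08), Gpc3 (-1.89) and Dpep1 (-1.36) ended. Mmp3 (0 UMIs in MI) was at least 47.9-fold higher there and lost its call (adjusted p = 0.0501). The medians of the activated and collagen lists were then 0.19 and 0.14 and their calls remained (adjusted p = 0.00787 and 8.94e-05), while the hypoxia median turned to -0.04. The count was 128 without MI replicate 1, 91 without MI replicate 2, 127 without MI-stiff replicate 1 and 220 without MI-stiff replicate 2. Tnn, Tnc, Postn, Fn1, Adam12, Timp1 and Mmp3 kept their calls in each case. Runx2 lost its call without MI replicate 2 (0.72), MI-stiff replicate 1 (0.82) or MI-stiff replicate 2 (0.81), Col6a3 without MI replicate 2 (0.93), Gpc3 without MI replicate 2 (-2.01), MI-stiff replicate 1 (-3.03) or MI-stiff replicate 2 (-2.11), and Dpep1 without MI replicate 2 (-1.26) or MI-stiff replicate 1 (-1.34). The interferon list lost its call without MI replicate 2 (median -0.17, adjusted p = 0.479) and the homeostatic list without MI-stiff replicate 1 (median -0.20, adjusted p = 0.109). Medians in these nuclei were 1.49 for smooth muscle markers (3 of 9 rose), 0.82 for macrophage markers (1 of 12 rose) and -3.78 for mast cell markers (2 of 4 fell).

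MI-stiff vs MI-soft changed 32 genes in fibroblast-like nuclei, 28 higher and 4 lower, against 312 by DESeq2 and 61 without the low-count filter. Adam12 rose by 1.96 ± 0.26 (adjusted p = 0.0339), the kinesin gene Kif26b by 1.89 ± 0.18 (adjusted p = 0.013), Postn by 1.74 ± 0.21 and Tnc by 1.29 ± 0.17, and the glutamine carrier gene Slc38a1 fell by 1.05 ± 0.12. Fn1 (1.23 ± 0.21, adjusted p = 0.0718) and Comp (-0.79 ± 0.27) did not pass. Calls of the activated (3 rose, 8 and 2 lower adjusted over the list alone; median 0.50, adjusted p = 7.78e-09), matrifibrocyte (3 lower adjusted over the list alone; median -0.51, adjusted p = 1.21e-04), protease (1 rose, 2 adjusted over the list alone; median 0.30, adjusted p = 0.00936) and hypoxia lists (3 rose adjusted over the list alone; median 0.35, adjusted p = 3.78e-05) were lost, with adjusted p = 0.0844, 0.0844, 0.0886 and 0.0886 with an estimated correlation. The other 6 lists were not called (adjusted p of 0.0721 or more), with collagens at a median of 0.05. Without cluster 9, 0 genes passed by edgeR, the activated (median 0.06), protease and hypoxia calls ended, the collagen (median -0.21), TGF-beta (-0.09, adjusted p = 0.00667) and mechanotransduction lists (-0.06, 0.0268) were called lower, and values were 0.49 for Adam12, 0.18 for Kif26b, 0.46 for Postn, -0.33 for Tnc and -0.66 for Slc38a1. The count was 0 without MI-soft replicate 1, 0 without MI-stiff replicate 1, 7 without MI-stiff replicate 2, 21 without Sham replicate 1 and 19 without Sham replicate 2. Kif26b lost its call without MI-soft replicate 1 (1.69), MI-stiff replicate 1 (1.84) or MI-stiff replicate 2 (1.93). Without either MI-soft library and then either MI-stiff library, Postn (1.60, 1.90, 1.75 and 1.73), Tnc (1.30, 1.28, 1.49 and 1.05) and Slc38a1 (-1.01, -1.09, -1.12 and -0.98) lost theirs. Tnc also lost it without Sham replicate 1 (1.29) or Sham replicate 2 (1.28), and Fn1 passed without Sham replicate 1 (1.23) or the low-count filter (1.21). Adam12 lost its call without MI replicate 2 (1.95), MI-soft replicate 1 (1.62), MI-stiff replicate 1 (1.82), MI-stiff replicate 2 (2.08) or Sham replicate 2 (1.95). The protease list lost its call without MI-stiff replicate 2 (median 0.16, adjusted p = 0.064).

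**Figure D4:**
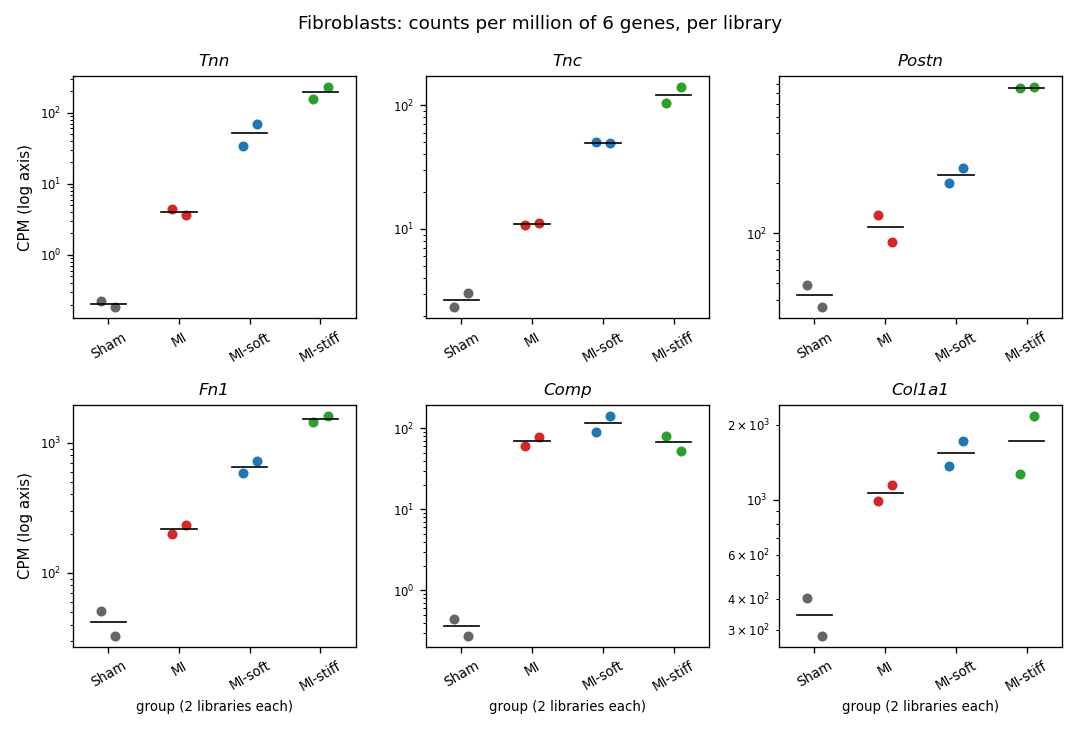
Levels of 6 genes in fibroblast-like nuclei (CPM, log y axis) by group (x axis), where dots are libraries and lines are means of 2 libraries. Tnc stood at 10.8 and 11.1 CPM in MI, 50 and 49.3 in MI-soft and 103 and 140 in MI-stiff.

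In cardiomyocyte-like nuclei the gel comparisons gave 0 genes by the edgeR test. MI-soft vs MI had 847 genes at an unadjusted p under 0.05, 14 by DESeq2 and 212 without the low-count filter. Fam78b (2.10 ± 0.33) and Efna5 (-1.58 ± 0.26) had the smallest p (adjusted p = 0.285 each), Myh6 was at 1.00 ± 0.39, Nppa at -0.50 ± 0.24 and Slc27a1 at 1.21 ± 0.41, and none of the 11 lists was called (adjusted p of 0.777 or more). MI-stiff vs MI had 946 genes at an unadjusted p under 0.05, 55 by DESeq2 and 270 without the filter. Txnip, which limits glucose uptake, was at 2.76 ± 0.35 (359 and 751 CPM against 97.5 and 64.5) and Fam78b at 2.58 ± 0.34 (adjusted p = 0.0702 each), and Cbr1l2 at 2.43 ± 0.34 (adjusted p = 0.0801). The fatty acid oxidation list was called higher (median 0.38, 0 rose, 4 adjusted over the list alone, adjusted p = 1.68e-04), a call lost at adjusted p = 0.946 with an estimated correlation, with Slc27a1 at 2.00 ± 0.42, Acaa2 at 1.23 ± 0.29 and Hadh at 1.17 ± 0.36. It ended without MI replicate 2 (median 0.12, adjusted p = 0.504) and without MI-stiff replicate 2 (median -0.05, adjusted p = 0.737), where oxidative phosphorylation was called lower (median -0.41). Nppa was at -0.69 ± 0.24 and Myh6 at 0.40 ± 0.39, and the other 10 lists were not called (adjusted p of 0.389 or more). MI-stiff vs MI-soft had 706 genes at an unadjusted p under 0.05, 4 by DESeq2 and 154 without the filter, with Tafa2 at -1.52 ± 0.28 and Col19a1 at 3.08 ± 0.59 (adjusted p = 0.626 each). The fatty acid oxidation list was called higher (median 0.40, 0 rose, 1 adjusted over the list alone, adjusted p = 2.8e-04; adjusted p = 0.971 with an estimated correlation), which turned without MI-stiff replicate 2 (median -0.09), and the other 10 were not (adjusted p of 0.388 or more). Macrophage markers were at a median of 1.03 in MI-soft vs MI and 1.51 in MI-stiff vs MI in these nuclei.

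In endothelial-like nuclei the gel comparisons gave 0 genes by the edgeR test. MI-soft vs MI had 641 genes at an unadjusted p under 0.05, 4 by DESeq2 and 4 without the low-count filter. Tnn was at 3.81 ± 0.57 and the mast cell protease gene Mcpt1l1 at -4.20 ± 0.69 (adjusted p = 0.575 each), and Vcam1 at 0.64 ± 0.16. Mast cell markers were at a median of -3.14 in MI-soft vs MI and -3.06 in MI-stiff vs MI, those of T and NK cells at 0.68 and 1.02 and those of macrophages at 0.15 and 0.82, and none passed. Lists called were immediate early (median 0.37, adjusted p = 5.84e-04), adhesion (0.36, 1 rose adjusted over the list alone, 0.0108), mesenchymal transition (0.24, 0.0196) and interferon (-0.18, 0.0352), all lost, with adjusted p = 0.565, 0.48, 0.48 and 0.565 with an estimated correlation. All 4 calls ended without MI-soft replicate 2, and those of mesenchymal transition, interferon (median 0.10) and immediate early ended without MI replicate 2, adhesion without MI replicate 1 and interferon without MI-soft replicate 1. MI-stiff vs MI had 1267 genes at an unadjusted p under 0.05, 148 by DESeq2 and 123 without the filter. Timp1 was at 1.64 ± 0.20 (adjusted p = 0.119), with 198 and 192 CPM against 62.6 and 62.2, the apelin receptor gene Aplnr at 1.54 ± 0.43, Vcam1 at 0.72 ± 0.16 and the venous gene Ackr1 at 1.38 ± 0.42. The immediate early (median 0.55, 1 rose adjusted over the list alone, adjusted p = 1.53e-04), adhesion (0.34, 3 rose adjusted over the list alone, 6.22e-04) and capillary lists (0.64, 0.022) were called and lost, with adjusted p = 0.625, 0.577 and 0.625 with an estimated correlation. The capillary call ended without MI-stiff replicate 2 (median -0.24) or MI replicate 2 (0.15) and the immediate early call without MI replicate 2 (0.24). MI-stiff vs MI-soft had 1072 genes at an unadjusted p under 0.05, 75 by DESeq2 and 65 without the filter, with Reep1 at 1.29 ± 0.19, Vcan at -1.44 ± 0.23 (adjusted p = 0.369 each) and the fenestration gene Plvap at 2.18 ± 0.53 (155 and 40.4 CPM against 20.9 and 22.3). The other lists were not called (adjusted p of 0.077, 0.354 and 0.333 or more in the 3 comparisons). Without MI-stiff replicate 2, 186 genes passed in MI-stiff vs MI and 139 in MI-stiff vs MI-soft. Without MI replicate 1 the counts in the 3 comparisons were 1, 17 and 6.

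In mural-like nuclei the gel comparisons gave 0 genes by the edgeR test. MI-soft vs MI had 601 genes at an unadjusted p under 0.05, 2 by DESeq2 and 110 without the low-count filter. Vcan was at 1.08 ± 0.19, Col12a1 at 1.00 ± 0.19 and Pgm5 at -2.18 ± 0.39 (adjusted p = 0.46 each). The collagen list was called higher (median 0.38, 5 rose adjusted over the list alone, adjusted p = 3.11e-09) and the contractile list lower (-0.35, 1.94e-05), both lost, with adjusted p = 0.216 and 0.415 with an estimated correlation, and the contractile call ended without MI-soft replicate 1 (median -0.27, adjusted p = 0.0511). MI-stiff vs MI had 652 genes at an unadjusted p under 0.05, 24 by DESeq2, 181 without the filter and 19 with predicted doublets kept. The growth factor gene Nrg1 was at -2.15 ± 0.27, the macrophage gene Lyz2 at 3.18 ± 0.44 and Timp1 at 1.32 ± 0.19 (adjusted p = 0.0608 each), Col12a1 at 1.25 ± 0.19 and Tnc at 2.73 ± 0.61, and macrophage markers were at a median of 0.73. The collagen (median 0.17, 5 rose adjusted over the list alone, adjusted p = 0.0113), interferon (-0.45, 0.0113) and immediate early lists (0.10, 1 rose adjusted over the list alone, 0.0322) were called and lost, each with adjusted p = 0.453 with an estimated correlation. Calls ended for collagens without MI replicate 1 or MI-stiff replicate 2, for interferon without MI replicate 2 and for immediate early without MI replicate 2 (median -0.16) or MI-stiff replicate 1. MI-stiff vs MI-soft had 674 genes at an unadjusted p under 0.05, 6 by DESeq2 and 141 without the filter, with the protease inhibitor gene Pi15 at 1.82 ± 0.25 (adjusted p = 0.116), Nampt at 1.59 ± 0.27 and Vcan at -1.01 ± 0.20. The collagen list was called lower (median -0.18, 3 fell adjusted over the list alone, adjusted p = 0.0124) and the contractile list higher (0.30, 6.72e-05), both lost at adjusted p = 0.699 with an estimated correlation. Without MI-stiff replicate 1 both calls ended, as they did without MI-soft replicate 2 for collagens and MI-soft replicate 1 for the contractile list. The other lists were not called (adjusted p of 0.069, 0.362 and 0.216 or more in the 3 comparisons).

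The changes of both gels against the same MI libraries were compared across genes, which are not independent replicates. Their correlation over all genes tested was 0.875 in macrophage-like nuclei, 0.648 in fibroblast-like, 0.530 in cardiomyocyte-like, 0.471 in mural-like and 0.451 in endothelial-like nuclei. Simulated groups without a difference, which share their MI libraries too, gave means of 0.603, 0.482, 0.437, 0.446 and 0.462 in the same order, and the covariance exceeded the simulated one by 0.432, 0.113, 0.0895, 0.0186 and 0.0213. With 1 MI library on each side the correlation was 0.638 and 0.538, 0.384 and 0.201, 0.127 and 0.188, 0.0607 and 0.00288, and -0.0101 and 0.0401. Of the genes that rose in macrophage-like nuclei, 412 with the soft and 997 with the stiff gel, 402 were the same. Of those that fell, 133 and 644, 128 were the same. In fibroblast-like nuclei 6 of the 7 and 401 higher genes were the same and 1 of the 1 and 90 lower genes.

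The share of the MI vs Sham change that remained with a gel was measured by regression over the genes changed in MI vs Sham, with the MI libraries split between the axes, where 100% is no movement back towards Sham. In cardiomyocyte-like nuclei it was 90.8% ± 6.59 with the soft gel (SD of the treated libraries, n = 2) and 88.9% ± 15.2 with the stiff gel. It was 98.8% ± 10.1 and 107% ± 3.48 in fibroblast-like, 95% ± 8.88 and 108% ± 8.86 in endothelial-like, 98.3% ± 10.4 and 103% ± 1.53 in macrophage-like and 93.3% ± 11.2 and 99.9% ± 11.2 in mural-like nuclei. In simulated data with a true value of 100% the estimate was 0.940 to 0.968 of it. No test was run on these shares.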

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

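No test was chosen for the shares in this part, and they lie outside the 5 classes that were compared. Each is a class of nuclei whose 2 libraries in an infarct group both stood at more than 2 times the higher Sham library. Nuclei with Schwann and neural markers made up 2.14% of nuclei in MI (1.68% and 2.61%), against at most 0.716% in Sham. Nuclei with dendritic cell markers made up 0.919% in MI (0.645% and 1.19%) and 0.702% in MI-soft (0.649% and 0.756%), against at most 0.206% in Sham. Nuclei with mesothelial markers, which line the outer surface of the heart, made up 4.09% in MI (1.63% and 6.55%), 0.16% in MI-soft (0.0942% and 0.226%) and 0.218% in MI-stiff (0.198% and 0.239%), against at most 0.0086% in Sham. An unnamed cluster, whose top genes over the other classes were macrophage genes (Apobec1, Aoah, Clec4a2 and Tlr7) and whose nuclei held 1.83 times the median UMIs of their libraries, made up 2.11% in MI-soft (1.87% and 2.35%), against at most 0.276% in Sham. Each group has 2 libraries, so these differences rest on 2 values a side. No biological or technical explanation of them was tested.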

How the results depend on the processing

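The tests listed at the start as added were chosen after the results were seen. Every alternative set beforehand was run. Over all results reported, 4725 of 5356 values under an alternative kept their direction and side of the threshold (or stayed within the limits for counts and values), and 14 reversed. Over the 40 results that answer a comparison it was 297 of 418. Relative log expression size factors changed no count past the limit. With 2 libraries per group, a left-out library leaves a lone one that is assumed to vary like the other groups, and fewer degrees of freedom lower most counts by construction; for the other changes the cause was not tested. The lowest depth of a class was 674569 UMIs, in cardiomyocytes of MI-stiff replicate 1. By the simulated data, a count of 0 does not show that no gene changed.

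Counts of changed genes are given in the order soft vs MI, stiff vs MI and stiff vs soft, where the value moved. Without the low-count filter they were 212, 270 and 154 in cardiomyocytes, 18 (soft) and 61 (stiff vs soft) in fibroblasts, 4, 123 and 65 in endothelial cells (1538 for MI vs Sham), and 110, 181 and 141 in mural cells. With DESeq2 they were 14, 55 and 4 in cardiomyocytes, 261, 805 and 312 in fibroblasts, 4, 148 and 75 in endothelial cells, 66 for stiff vs soft in macrophages, and 2, 24 and 6 in mural cells. With predicted doublets kept, mural cells gave 19 for stiff vs MI. Without genes at the level of free RNA, macrophages gave 417 for MI vs Sham. Without cluster 9 fibroblasts gave 4, 5 and 0, and without cluster 17 macrophages gave 1 and 288 for soft and stiff vs MI. With the replicate block the counts were 1 and 6 in cardiomyocytes and 1 and 11 in endothelial cells for soft and stiff vs MI, 15 for soft vs MI in fibroblasts, and 1 and 17 in mural cells; replicate numbers did not pair the libraries, whose deviations correlated between groups at -0.411 to 0.331.

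With each library left out in turn, MI vs Sham gave 1250 to 3070 genes in cardiomyocytes, 1576 to 2918 in fibroblasts, 60 to 1229 in endothelial cells, 91 to 876 in macrophages and 1500 to 2691 in mural cells. Soft vs MI gave 0 to 1 in cardiomyocytes, 0 to 9 in fibroblasts, 0 to 1 in endothelial cells and 215 to 612 in macrophages. Stiff vs MI gave 0 to 36, 91 to 420, 0 to 186, 851 to 1469 and, in mural cells, 0 to 5, and stiff vs soft gave 0 to 7, 0 to 42, 0 to 139 and, in macrophages, 0 to 51. The adjusted p of the macrophage share was 0.0476 to 0.0952 (exact permutation). The correlation of both gels' changes was 0.384 to 0.686 in cardiomyocytes, 0.467 to 0.743 in fibroblasts, 0.263 to 0.651 in endothelial cells, 0.788 to 0.899 in macrophages and 0.324 to 0.646 in mural cells. With soft against MI replicate 1 and stiff against MI replicate 2, and then the other way, it was 0.127 and 0.188, 0.384 and 0.201, -0.0101 (reversed) and 0.0401, 0.638 and 0.538, and 0.0607 and 0.00288; without shared libraries the part that MI noise adds is gone by construction. With both MI libraries on both axes the share remaining in macrophages with the stiff gel was 101%.

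The 13 other results labelled reversed were lists, given by their medians, and the gene Tnc. The first 9 stood under a left-out library, with the range over left-out libraries in brackets. Without MI-stiff replicate 2, cardiomyocyte oxidative phosphorylation was at -0.41 (-0.41 to 0.32) in stiff vs MI and -0.35 (-0.35 to 0.31) in stiff vs soft, fatty acid oxidation at -0.089 (-0.089 to 0.71) in stiff vs soft, and mural contractile and pericyte genes at 0.30 and -0.28 (-0.28 to 0.30 and -0.28 to 0.33) in stiff vs MI. Without MI replicate 2, interferon genes were at 0.039 (-0.94 to 0.039) in fibroblasts and 0.10 (-0.48 to 0.10) in endothelial cells for soft vs MI, and endothelial capillary genes at -0.39 (-0.39 to 1.49) for soft vs MI and 0.15 (-0.24 to 1.75) for stiff vs MI, where the test pointed down. Without cluster 9, fibroblast hypoxia genes were at -0.036 (stiff vs MI), collagens at -0.21, activated genes at 0.058 with a test pointing down, and the gene Tnc at -0.33 (stiff vs soft).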

Other observations

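In this part the tests of doublets, of neighbours and of free RNA from cardiomyocytes were chosen after the result was seen; the others were set first. In fibroblast-like nuclei Angptl4, a lipase inhibitor induced by fatty acids and low oxygen, rose with the stiff gel by 2.37 ± 0.28 against MI (edgeR adjusted p = 0.00694), from 12.3 and 11.8 CPM to 60.9 and 64.2, and by 2.19 ± 0.28 against the soft gel (adjusted p = 0.0292). In cardiomyocyte-like nuclei Pdk4, which turns glucose oxidation down, was at 4.16 ± 0.69 against MI without passing (adjusted p = 0.0946), and its MI-stiff libraries differed (60.3 and 357 CPM against 15 and 6.45).

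Genes at least 5 times higher in macrophage-like nuclei than in every other main class had medians above 0 with the stiff gel in the other classes too: 1.15 in fibroblasts (54 of 290 rose), and 0.67 in endothelial cells, 0.83 in mural cells and 0.89 in cardiomyocytes (0 called in each), against 0.18 in macrophages themselves (101 of 294 rose). Doublets that join a macrophage to another nucleus are argued against: a minority of nuclei would lift the mean share of these genes per nucleus and not its median, but the median rose by at least 83.1% of the mean's log2 rise in these 4 classes, from 0.221% and 0.255% to 0.394% and 0.409% in fibroblasts. For RNA released by macrophages, 75.9% of 294 genes had UMIs per nucleus within 2-fold between endothelial and mural cells, between the bounds of 80% and 50% set for and against it. Free RNA may explain part of the rise. It cannot be told apart from the choice of genes, expression in these classes or a change in macrophages. The share of macrophages rose with the same groups.

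Most Sham nuclei lay in clusters of their own in each main class. A difference between library batches that moves every cell type was weighed against the infarct itself. T and NK cells showed 251 changed genes in MI vs Sham outside free RNA, against 388 in macrophages to 1523 in mural cells thinned to the same depth. This was a median of 24.2%, from 16.5% of the number in mural cells to 64.7% in macrophages. The bounds set were at least 50% of each class for a batch and under 20% of at least 4 classes against it, and neither was met. Sham T and NK cells (451 and 396 nuclei) shared a cluster with infarct ones, as did B, dendritic, Schwann, lymphatic and endocardial cells, which speaks against a batch. But where 40 Sham and 40 MI nuclei of a type were drawn, 66.5% (dividing cells) to 88.5% (endocardial cells) of the 10 nearest neighbours came from the same group, against 82.9% in macrophages to 97.5% in fibroblasts. The bounds were every other type at 82.9% or more for a batch and below each main class against it. Neither was met, so a batch and the infarct cannot be told apart, as the labels name no batch and the groups would follow it.

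The fuel-use genes Pdk4, Angptl4 and Txnip were singled out from a panel of 28 genes looked at first. For free RNA from cardiomyocytes, the rise of Angptl4 over MI would need 44.3% to 202% of a class's RNA. This is at least 7.42 times the share by cardiomyocyte markers (1.01% to 7.85%). Txnip needed 1.39 (mural cells, MI-stiff replicate 2) to 79.5 times that share in 8 values (bound of 2), and Pdk4 as little as 0.357 (macrophages). The test takes free RNA to match cardiomyocyte nuclei, which was not checked. Free RNA and expression in the class cannot be told apart for these genes. For a difference in fatty acid supply or feeding state, other fatty acid responsive genes had a median of 0.57 in cardiomyocytes (7 of 10 tested, 0 called), but -0.11 in fibroblasts, 0.20 in endothelial cells, -0.33 in macrophages and 0.00 in mural cells. A supply difference that acts on cardiomyocytes may be part of it, and it cannot be told apart from an effect of the stiff gel, as both would separate the same libraries.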
